A study of Rattus norvegicus with 6 samples.

How the data were processed

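Rat heart RNA was measured on 6 one-colour Agilent arrays with 45018 spots each, of which 43379 were not controls and together held 41012 probes. Per the labels, total RNA was labelled with Cy3, and each of the sham, MI and MI+TPO groups had 2 biological replicates. Spot intensity was extracted with Agilent Feature Extraction 9.5.3.1 for the sham and MI arrays and 10.1.1.1 for the MI+TPO arrays, per the file headers. The submitters' processing notes name Feature Extraction 9.1. The processed signal used here is a linear intensity that was background-subtracted and detrended within each array, per the file headers, with no scaling between arrays. The sham and MI arrays merged a high and a low scan and the MI+TPO arrays did not, per the file headers. Other columns used, per the file headers, were flags of 0 or 1 for spots that were saturated, uneven, out of line with their replicate spots or well above background. The deposited value table is on a log2 scale. Set against the scanner values, it held the log2 processed signal scaled by the 75th percentile and centred per probe, and it served as an alternative only.

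Uneven and out-of-line spots were left out, between 0.214% and 0.353% of the spots of an array. The log2 processed signal was averaged over the spots of a probe, and the array's 75th percentile was subtracted. That percentile lay between 331 and 426 on the sham and MI arrays and at 604 and 773 on the MI+TPO arrays. Local background lay between 86 and 90.5 on the former and at 45.5 and 46 on the latter. Probes were kept if well above background on both arrays of at least 1 group, which left 23643, less 52 with a missing value. For the 2984 genes with several probes, the probe with the highest mean over the 6 arrays was taken, giving 19932 features, 10161 of them with a gene symbol. Symbols came from the reference table of gene names by accession for 11103 probes, by current symbol for 5440 and by an older symbol for 3624, and 20845 kept the name in the files. For 69 probes accession and name pointed to different genes. Probe positions are those of the sham and MI array files, on rn3.

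All 6 arrays were fitted together with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 1 coefficient per group and 3 residual degrees of freedom. The prior had 2.95 degrees of freedom and an SD of 0.282. Tests were two-sided, with Benjamini-Hochberg adjustment over all features of a comparison and a threshold of 0.05. The 3 comparisons were MI against sham, MI+TPO against MI and MI+TPO against sham. Before the data were examined, 38 gene lists were fixed, and the 37 with at least 4 measured members were tested with camera at its preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. The count adjusted over the list alone repeats the adjustment over a list's measured members. Tables were prepared with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6.

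The genes named were set by a rule fixed before the data were examined. For MI against sham and MI+TPO against MI it took the 12 largest rises and 12 largest falls with a symbol past the threshold, with arrays of the groups not overlapping and a signal well above background on both arrays of the brighter group. Where fewer than 3 passed, the 5 with the smallest unadjusted p were taken and said to have missed. For MI+TPO against sham it took 5 each way. Rank was by fitted log2 fold change, also for probes whose fold is given only as a bound. It added up to 4 members of each called list with the smallest p in its direction, up to 6 genes called in opposite directions by MI and by TPO, and Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Col1a1, Col3a1, Postn, Timp1, Spp1, Mpl and Bcl2l1. Other genes named from the lists, or as exceptions within them, were chosen after their values were seen.

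A fold against a group in which a probe was well above background on no array is a lower bound, computed against the dimmest signal well above background. Where 1 array of the dimmer group was below that signal, the named fold is bounded by setting that array to it. The fit was tested on simulated data, 50 genes changed per size. Each gene had a spread drawn from the fitted prior, equal in all groups, and genes were independent. For MI against sham the fit recovered 34% at a log2 fold change of 2 and 76% at 3, for MI+TPO against MI 40% and 80%, and for MI+TPO against sham 44% and 80%. Of 113 simulated calls in MI against sham, 9 were of unchanged genes. The real groups differed in spread (median SD 0.125 in sham, 0.219 in MI and 0.315 in MI+TPO), so these rates may not hold for them.

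Alternatives were other background corrections, scalings, filters, choices of probe, fits and thresholds, a replicate block, and leaving out each array in turn. Shared arrays were examined with 100 simulations of unchanged groups. Each group lay on its own slide, so no fit with slide as a term can separate slide from group. The number of arrays limits the precision.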

Results

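Gene expression in the rat heart was measured on 6 one-colour Agilent arrays, 1 per sample, in 3 groups of 2 biological replicates. The groups were sham surgery with saline, myocardial infarction (MI) by ligation of the left coronary artery with saline, and MI with thrombopoietin (TPO), all at week 4. TPO, the hormone that drives platelet production through its receptor Mpl, was injected intraperitoneally at 10 µg/kg directly after MI and then 3 times weekly for 2 weeks. The sample labels call the tissue whole heart in one field and left ventricle in another, so the part of the heart sampled is not settled. Each array carried 41012 probes, of which between 50.7% and 58.7% were well above background on a given array. MI replicate 1 had the lowest share (50.7%) and the fewest spots found, 36233 against between 40751 and 43296 on the others. Its negative control spots had the largest SD, 9.04 against between 5.08 and 6.79. Whether this bears on the results that hang on MI replicate 1 was not tested. With 2 arrays per group, the number of arrays limits the precision of every value.

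Levels are log2 signals relative to the array's 75th percentile, given as mean ± SD (n = 2), and a ± after a log2 fold change is its SE. Positions are probe positions on the rat assembly rn3, as the array files give them. An adjusted p is limma's over 19932 features unless it is said to be adjusted over a list alone. Where a probe was not well above background on a whole group, only a lower bound of the fold is given, set against the dimmest signal well above background. Each group was hybridised on its own slide, and the MI+TPO arrays were also read by another scanner model, so slide and group cannot be told apart in any comparison below.

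The arrays of a pair were not equally close. Across genes, the log2 signals of the sham pair correlated at 0.992, those of the MI pair at 0.981 and those of the MI+TPO pair at 0.968. MI+TPO replicate 1 correlated at 0.953 with MI replicate 1 and 0.936 with sham replicate 1, while MI+TPO replicate 2 correlated at 0.928 with MI replicate 1 and 0.968 with sham replicate 1. The median SD between the arrays of a pair was 0.125 in sham, 0.219 in MI and 0.315 in MI+TPO. On an axis from sham (0) to MI (1) drawn with the other arrays, MI replicate 1 lay at 0.94, MI replicate 2 at 0.61, MI+TPO replicate 1 at 0.57 and MI+TPO replicate 2 at 0.07. The ranges of MI replicate 2 (0.56 to 0.67) and MI+TPO replicate 1 (0.51 to 0.65), over the arrays that define the axis, overlapped. Genes are not independent replicates, so these correlations describe the arrays only.

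The first comparison asked what differed between infarcted and sham-operated hearts. In MI hearts the genes of the extracellular matrix were higher together, and those of fatty acid oxidation and the respiratory chain were lower together, as lists whose calls ended with an estimated correlation (adjusted p between 0.61 and 0.669). Spp1 (osteopontin, a matrix protein made by macrophages and fibroblasts; chromosome 14, 6422382 to 6422441) had a level of 5.29 ± 0.13 (SD, n = 2) in MI and -0.23 ± 0.23 (SD, n = 2) in sham, a 45.9-fold difference. Postn (periostin, a marker of activated fibroblasts; chromosome 2, 143510755 to 143511791) was 29.4-fold higher and Nppa (atrial natriuretic peptide; chromosome 5, 165084824 to 165084883) 20.1-fold higher, the latter at 7.72 ± 0.06 (SD, n = 2) against 3.4 ± 0.61 (SD, n = 2). None of these 3 genes passed over all genes (adjusted p between 0.0882 and 0.0954), and all 3 passed when adjusted over the list alone.

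**Figure D1:**
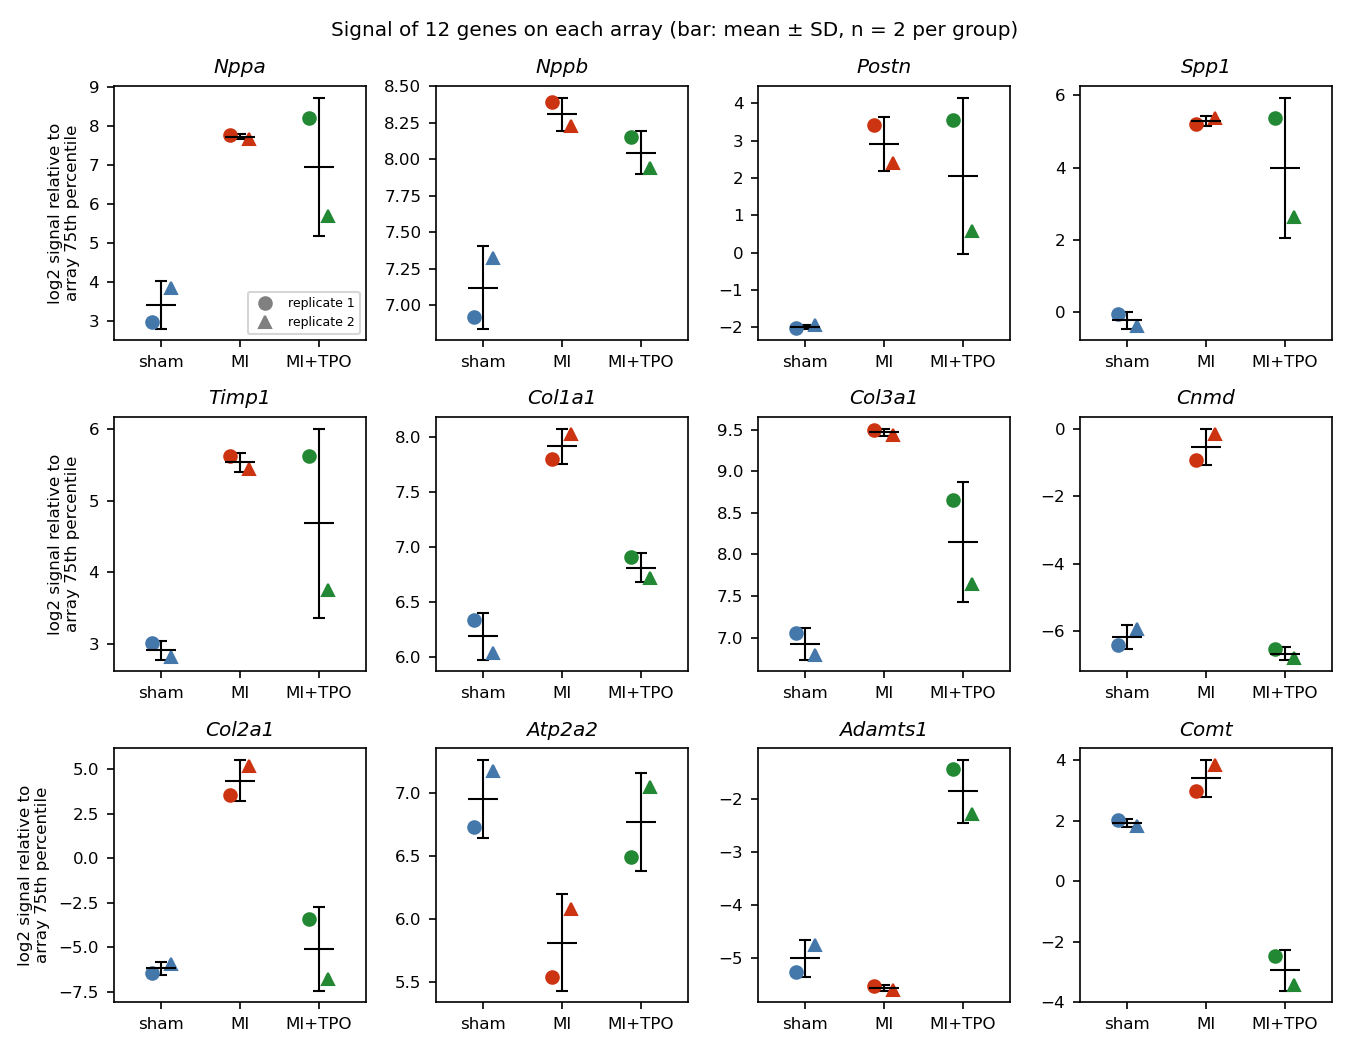
Log2 signal relative to the array's 75th percentile (y axis) of 12 genes in the sham, MI and MI+TPO groups (x axis), with circles for replicate 1, triangles for replicate 2 and bars for the mean ± SD (n = 2). Cnmd and Col2a1 were high on both MI arrays and low on the others, while for Nppa, Postn, Spp1 and Timp1 the MI+TPO arrays lay apart, with Nppa at 8.21 on replicate 1 and 5.69 on replicate 2.

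Of 37 gene lists tested with limma's camera, 21 passed in MI against sham, 15 higher and 6 lower. No list kept its call with an estimated correlation (adjusted p between 0.61 and 0.669 for these 21) or with the rotation test fry (smallest adjusted p 0.136). All 41 measured members of the list of collagens and other matrix genes were higher, with a median log2 fold change of 2.11, or 2.06 with 1 member at its bound (adjusted p = 3.12e-20). Of these, 38 rose when adjusted over the list alone and 0 over all genes, where limma gave 5801 features at an unadjusted p under 0.05. Examples were Col3a1 at 2.54 ± 0.37 and Col1a1 at 1.73 ± 0.23, the fibrillar collagens of scar, and the other probes of Col1a1 gave 3.34 and 3.38. Among matrix proteases and their inhibitors, 15 of 21 members (16 of the 19 above background on any array of either group) rose when adjusted over the list alone (median 1.98, adjusted p of the list 1.15e-09). They included Timp1, an inhibitor of matrix metalloproteinases, at 2.62 ± 0.58, Timp3 at 1.87 ± 0.23, and Mmp12 (macrophage elastase), which was at least 47-fold higher (adjusted p = 0.0502 over all genes). Smooth muscle and myofibroblast genes gave a median of 1.44 (adjusted p = 0.000378), with 10 of 13 past the list alone, such as Actg2 (smooth muscle gamma actin) at 3.35 ± 0.81. TGF-beta signalling (median 0.59, adjusted p = 1.04e-05) and basement membrane (median 0.43, adjusted p = 0.00775) also passed as lists, with 0 of 22 and 1 of 13 members past the list alone.

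Some lists of immune genes were higher too, and others did not pass. Macrophage and monocyte markers were higher in all 22 measured members (median 1.56, adjusted p = 8.15e-10, 16 past the list alone), among them Gpnmb at 3.51 ± 0.54, the mannose receptor Mrc1 at 2.00 ± 0.39 and lysozyme Lyz2 at 2.28 ± 0.60. Complement and coagulation genes had a median of 1.43 (adjusted p = 1.88e-06) with 13 of 22 past the list alone, C3 leading at 4.05 ± 0.83 (3.33 without MI replicate 1 and 4.77 without MI replicate 2). Of 27 chemokines and cytokines, 7 rose and 3 fell when adjusted over the list alone (median 0.72, adjusted p of the list 0.00469). The lymphoid chemokines Ccl19 (2.86 ± 0.35) and Cxcl13 (4.51 ± 1.08) were among the higher members, and Cxcl11, Cxcl12 and Cxcl9 were the lower ones. MHC class II (median 1.04, adjusted p = 0.0162) and mast cell markers (1.22, adjusted p = 0.00462) passed as lists, with 3 of 7 and 1 of 9 past the list alone. The 3 of MHC class II hang on Ciita, which was well above background on no sham or MI array and gave -0.40 after normexp background correction: of the other 6 members 0 passed (smallest adjusted p 0.0569). Without MI replicate 1 the medians were 0.89 for complement and 0.59 for mast cells, which kept their calls, and the calls of chemokines (0.28) and MHC class II (0.71) ended, as did those of glycolysis (-0.57) and skeletal muscle (0.37) below. Lymphocyte markers (median 0.19, adjusted p = 0.648), neutrophil markers (-0.42, 0.204) and interferon-stimulated genes (0.06, 0.352) did not pass.

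Cartilage and bone genes showed the largest list median at 2.84, or 2.48 with 5 members at their bounds. Of 15 members, 13 rose when adjusted over the list alone (adjusted p of the list 1.21e-09). Some members had a clear signal on the sham arrays: Alpl at 2.77 and 2.3, Omd at 2.51 and 2.24, and Cilp at 2.02 and 2.46. Others, such as Col2a1, were well above background on no sham array. Col2a1, the main collagen of cartilage, was at least 403-fold higher (adjusted p = 0.0607 over all genes), or 718 without MI replicate 1 and 227 without MI replicate 2. Ibsp (bone sialoprotein) was at least 56.2-fold higher (84.6 and 37.4 without these arrays) and Sox9, the transcription factor of cartilage cells, gave 1.48 ± 0.23. Schwann cell and neuronal markers had a median of 1.32 (adjusted p = 0.000956) with 4 of 9 past the list alone, led by the myelin gene Mpz at 2.27 ± 0.35. Skeletal muscle markers had a median of 0.88 (adjusted p = 0.0105) with 3 of 9 past the list alone, which were Myl1, Mybpc2 and Tnnt3; its median was 1.39 without MI replicate 2, and its call ended after normexp background correction. Cell cycle genes (median 0.57, adjusted p = 0.00164) and immediate early genes (0.78, adjusted p = 0.000656) passed as lists with 0 members past the list alone. With members at their bounds, the medians were 0.67 for chemokines, 0.98 for MHC class II, 1.12 for mast cells, 1.41 for Schwann cell and neuronal markers, 0.60 for cell cycle and 0.74 for immediate early genes.

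Genes of energy metabolism were lower in MI. For fatty acid transport and oxidation the median log2 fold change was -1.51 (adjusted p = 4.82e-12), and 32 of 34 members fell when adjusted over the list alone. Examples were Ucp3, an uncoupling protein of muscle mitochondria, at -2.83 ± 0.63 (-1.91 without MI replicate 1 and -3.74 without MI replicate 2), the dienoyl-CoA reductase Decr1 at -1.84 ± 0.34 and the electron transfer flavoprotein Etfa at -1.34 ± 0.29. The respiratory chain and ATP synthase fell in 53 of 57 members (median -1.08, adjusted p of the list 9.1e-16), with Ndufs6 at -1.48 ± 0.28 and Atp5f1b at -1.51 ± 0.31, and the list of citric acid cycle and branched-chain amino acid breakdown in 23 of 26 (median -1.20, adjusted p of the list 2.66e-08), each adjusted over the list alone. Glycolysis was mixed within a median of -0.81 (adjusted p = 0.0147). Adjusted over the list alone, 13 of 26 members fell, including the muscle enzymes Aldoa, Pgam2 and Pfkm, and 3 rose (Eno2, Pfkp and the lactate transporter Slc16a3); its list call ended with quantile normalization. Calcium handling and ion channels fell in 20 of 22 members (median -1.27, adjusted p of the list 2.9e-06), among them the potassium channel Kcnh2 at -2.28 ± 0.37 and the gap junction gene Gja1 at -1.30 ± 0.36, and only Kcnd3 rose, adjusted over the list alone. Sarcomere genes passed as a list (median -1, or -0.62 without MI replicate 1; adjusted p = 0.000108), with 0 of 17 past the list alone. With no filter on dim probes the calls of basement membrane, mast cells, chemokines, MHC class II, cell cycle, immediate early and skeletal muscle genes ended, and the other 14 of the 21 were kept. With probes above background on all arrays the MHC class II call ended.

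Among genes commonly read as markers of cardiac stress, Myh7 and Acta1 differed between MI and sham by less than their SE, and others differed by more. Myh7 gave -0.03 ± 0.23 and Acta1 -0.01 ± 0.36, both of which turn positive with quantile normalization (0.04 and 0.14), and Myh6 gave -0.25 ± 0.24. Nppb was 2.28-fold higher and rose when adjusted over the list alone. The calcium pump gene Atp2a2 gave -1.13 ± 0.32 (adjusted p = 0.108), while its other probes gave between -0.30 and -0.20. The list of natriuretic peptide and stress genes did not pass (median -0.01, adjusted p = 0.149), nor did endothelial markers (-0.17, 0.939), apoptosis genes (0.01, 0.726), TPO and JAK-STAT signalling (0.03, 0.677) or platelet markers (0.42, 0.0967). The probe of Mpl was not well above background on any of the 6 arrays, and the antiapoptotic gene Bcl2l1 gave -0.29 ± 0.21.

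**Figure D2:**
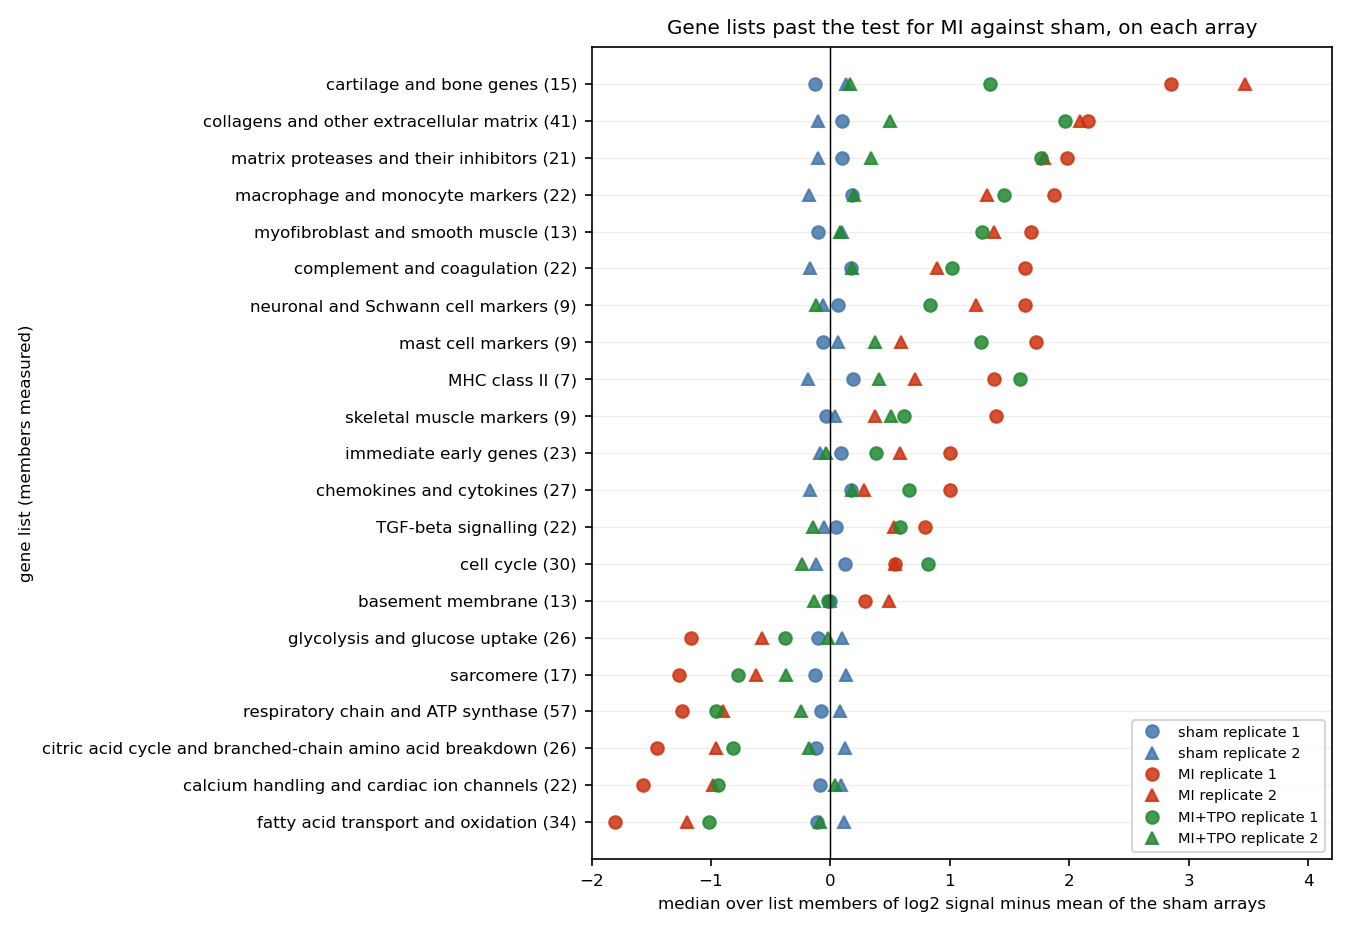
For each of the 21 gene lists past the test in MI against sham (y axis, measured members in brackets), the median over its members of each array's log2 signal minus the mean of the sham arrays (x axis), with colours for groups, circles for replicate 1 and triangles for replicate 2. In most lists MI+TPO replicate 1 lay near the MI arrays and replicate 2 near the sham arrays; glycolysis passed with the main scaling and not with quantile normalization.

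Over all 19932 features, limma called 7 in MI against sham, 6 higher and 1 lower (19 and 8 with quantile normalization), each at an adjusted p of 0.0437. Cnmd (chondromodulin, a cartilage matrix protein; chromosome 15, 60907045 to 60907104) was at least 13.6-fold higher, the neuronal gene Dcx at least 8.34-fold and Got1l1 at least 4.23-fold. After normexp background correction of all arrays 2 of the 7 calls were kept, those of Cnmd (1.18), Dcx (0.74), Got1l1 (0.33) and Dcdc1-ps1 (-1) being among the 5 that ended. Trh (thyrotropin-releasing hormone; chromosome 4, 126670185 to 126670244) rose by 4.99 ± 0.38 on the log2 scale, from -3.76 ± 0.26 (SD, n = 2) to 1.23 ± 0.19 (SD, n = 2). The transcripts AA926356 (3.33 ± 0.26) and AI231472 (3.28 ± 0.25), outside the naming rule and named because the count is small, also rose, and Dcdc1-ps1 was at least 1.6-fold lower. As fewer falls passed than the naming rule asks for, those of the smallest p are given, which missed the threshold: Ephx4 at -2.73 ± 0.26 (adjusted p = 0.0597), Crybb1 at least 1.75-fold lower, Them4 at least 1.87-fold lower and Dennd2c at least 1.04-fold lower.

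The count depended on which arrays shared the estimate of the spread: with the sham and MI arrays alone limma called 3972 features, without MI+TPO replicate 1 it called 3967 and without MI+TPO replicate 2 it called 3963. Without sham replicate 1, sham replicate 2, MI replicate 1 or MI replicate 2 it called 0, with 2930, 2139, 2473 and 4962 at an unadjusted p under 0.05, and the fit of all arrays had 5801 at that p where chance gives 997.

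The second comparison asked what differed between infarcted hearts with TPO and with saline. With TPO, genes of fatty acid oxidation and of the citric acid cycle and branched-chain amino acid breakdown were higher, and genes of cartilage, mesothelium and matrix were lower, as lists whose calls ended with an estimated correlation (adjusted p = 0.843). The 3 lower calls also ended without MI+TPO replicate 2. Bdh1, the mitochondrial enzyme of ketone body use (chromosome 11, 71188258 to 71188317), rose 8.12-fold, from -0.90 ± 0.34 (SD, n = 2) to 2.12 ± 0.72 (SD, n = 2; adjusted p = 0.0132). Col2a1 was at least 359-fold lower (chromosome 7, 136755658 to 136755717; adjusted p = 0.00948), with MI+TPO replicate 2, which was not well above background, set to the dimmest such signal. That fold was 640 without MI replicate 1, 202 without MI replicate 2, 591 without MI+TPO replicate 1 and 219 without MI+TPO replicate 2. Col1a1 fell by 1.1 ± 0.23 (chromosome 10, 83652547 to 83652606; adjusted p = 0.0399), from 7.92 ± 0.16 (SD, n = 2) to 6.82 ± 0.13 (SD, n = 2). Msln (mesothelin, a surface protein of mesothelial cells; chromosome 10, 15017206 to 15017265) fell by 3.19 ± 0.36 (adjusted p = 0.00864).

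Of the 37 lists, 10 passed in this comparison, 5 higher and 5 lower, none of them with an estimated correlation (adjusted p = 0.843 for all 10) or with fry (smallest adjusted p 0.15). All 34 members of fatty acid transport and oxidation were higher with TPO (median 0.97, adjusted p = 1.89e-07), and 9 rose when adjusted over the list alone, 4 of them over all genes. Examples were Acads, an acyl-CoA dehydrogenase, at 2.14 ± 0.43 and Etfa at 1.80 ± 0.29. The list of citric acid cycle and branched-chain amino acid breakdown had 24 of 26 members higher (median 0.76, adjusted p = 7.2e-05), with Bdh1, Sdhc at 1.63 ± 0.31 and Pdhb at 1.27 ± 0.26 past both thresholds. The respiratory chain had 48 of 57 members higher (median 0.49, adjusted p = 7.2e-05), 3 over all genes (Ndufs4, Ndufs6 and Atp5f1b) and 0 over the list alone. Glycolysis had a median of 0.54 (adjusted p = 0.0185), with Hk1 at 1.28 ± 0.24 and Eno1 at 1.25 ± 0.25 past both thresholds. Calcium handling and ion channels had 21 of 22 members higher (median 0.74, adjusted p = 0.00121). Of these, Kcnh2 rose by 3.65 ± 0.37, and Kcnd3 fell by 1.73 when adjusted over the list alone. When MI+TPO replicate 2 was left out, the medians were 0.42 for fatty acid oxidation and 0.29 for citric acid cycle and branched-chain breakdown, and the calls of the respiratory chain (0.10), glycolysis (0.20) and calcium handling (0.28) ended. The same 5 medians without MI+TPO replicate 1 were 1.49, 1.11, 0.90, 0.88 and 1.23, and without MI replicate 1 they were 0.63, 0.44, 0.35, 0.33 and 0.49, the last pair no longer called.

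The lower lists began with cartilage and bone genes, in which all 15 members were lower (median -1.11, adjusted p = 0.000852), 7 past the list alone and 5 over all genes. Ibsp was at least 40.5-fold lower, bounded the same way for MI+TPO replicate 2 (61 without MI replicate 1, 26.9 without MI replicate 2, 82.5 without MI+TPO replicate 1 and 19.9 without MI+TPO replicate 2), and Bglap (osteocalcin) was at least 13.3-fold lower. Among mesothelial and epicardial markers 10 of 12 were lower (median -1.41, or -1.31 with 1 member at its bound; adjusted p = 0.00755), 6 past the list alone (5 of the 11 above background on any array of either group), with the keratin Krt19 at -3.52 ± 0.39 and the uroplakin Upk1b at -2.35 ± 0.38. Of 41 matrix genes 39 were lower (median -0.94, adjusted p = 0.000455), and Col1a1 and Thbs2 (-1.35 ± 0.31) fell over all genes but not over the list alone. The call of Col1a1 ended after normexp background correction (-0.78) and with the mean of its probes (-1.32). In complement and coagulation 17 of 22 were lower (median -0.94, adjusted p = 0.0417). Of these, 3 fell and Tfpi, an inhibitor of coagulation, rose by 1.04 ± 0.24 when adjusted over the list alone, the falls being von Willebrand factor Vwf at -1.64 ± 0.21, complement factor Cfb at -2.13 ± 0.42 and F5 at -1.54 ± 0.33. TGF-beta signalling was lower in 19 of 22 (median -0.53, adjusted p = 0.0191), with Ski, a repressor of the pathway, at -1.20 ± 0.22 past the list alone. The calls of all 5 lower lists ended without MI+TPO replicate 2, with medians of -0.12 for matrix, -0.76 for cartilage and bone (-0.55 with the probes of the fit of all arrays kept), -0.93 for mesothelium, -0.40 for complement and -0.34 for TGF-beta signalling. These medians without MI+TPO replicate 1 were -1.70, -1.86, -1.88, -1.42 and -0.76. Without MI replicate 1 the calls of mesothelium (-1.16), complement (-0.64) and TGF-beta signalling (-0.47) ended. With no filter on dim probes the calls of all 5 lower lists ended, after normexp background correction that of TGF-beta signalling did, and with probes above background on all arrays that of cartilage and bone did.

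Over all features limma called 2102 in MI+TPO against MI, 883 higher and 1219 lower, or 42% higher. With quantile normalization 1088 were higher and 958 lower, or 53.2% higher. After normexp background correction 1131 were higher and 2606 lower (30.3% higher), and with no filter on dim probes 1418 and 9360 (13.2%). With no filter the median log2 fold change of all features was -0.522 here and 0.241 in MI against sham. The dimmest signal well above background was -3.62 and -3.67 on the MI arrays. On the sham arrays it was -4.55 and -4.06, and on the MI+TPO arrays -4.64 and -4.86. The balance of directions thus depended on the processing. The largest rises and falls below are ranked by fitted log2 fold change, which for dim probes includes values below background. Some of their bounds are therefore smaller than the measured folds of other called genes, such as Bdh1, Krt19 and Msln. The largest rises beside Kcnh2 were Kif19 (at least 8.56-fold), Hint3 (at least 5.21-fold), Ifna4 (at least 4.59-fold), Tsg101 (at least 4.56-fold), Fam184b (at least 3.74-fold), Adamts1, a protease of matrix proteoglycans (at least 3.48-fold), and Whamm (at least 3.45-fold). Gipc2 (3.98 ± 0.47, its other probe 0.58; without MI+TPO replicate 2 that other probe is the brighter, at 0.80, and the named one gives 3.39), Rchy1 (3.90 ± 0.28), Nsmce2 (3.58 ± 0.28) and the antiproliferative gene Tob1 (at least 10.6-fold) were well above background on at least 1 MI array. After normexp background correction the calls of Ifna4 (1.00), Fam184b (0.59), Whamm (0.64), Hint3 (0.93), Adamts1 (0.47) and Tsg101 (0.81) ended, and their log2 fold changes stayed positive. The largest falls beside Col2a1, Ibsp and Bglap were Comt (catechol-O-methyltransferase, which degrades catecholamines; chromosome 11, 84621999 to 84622058) at -6.36 ± 0.43 (adjusted p = 0.00573), Bnc1 (at least 18.5-fold lower), Cnmd (at least 18.4-fold), Mmp13 (at least 12.6-fold), the fibrinogen chain Fgg (at least 10.9-fold, its second probe -5.59), Clec3a (at least 7.78-fold), the cartilage link protein Hapln1 (at least 7.43-fold), Slc51a (at least 3.25-fold) and the neuropeptide gene Gal (-4.19 ± 0.89, or -2.74 without MI+TPO replicate 1 and -5.63 without MI+TPO replicate 2). Left without MI+TPO replicate 1 or 2, the bounds were 15.2 and 4.83 for Kif19 and 8.02 and 2.63 for Ifna4. Without MI replicate 1 or 2 they were 12 and 28.5 for Bnc1, 20.7 and 7.65 for Mmp13 and 12.4 and 4.45 for Hapln1, and that of Clec3a was 4.83 without MI replicate 2.

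Other genes with a known part in infarct healing did not pass in this comparison. Nppa gave -0.77 ± 0.80 (adjusted p = 0.537), Postn -0.84 ± 0.93, Timp1 -0.85 ± 0.58 and Spp1 -1.29 ± 0.83. Without MI+TPO replicate 2 all 4 turn positive, at 0.49, 0.63, 0.09 and 0.08. Nppb gave -0.26 ± 0.24 and its other probes between -1.34 and -1.22. Acta1 gave 1.52 ± 0.36 (adjusted p = 0.0532), Col3a1 -1.32 ± 0.37 (0.0748) and Atp2a2 0.95 ± 0.32 (0.114). Over the alternatives Atp2a2 gave between 0.47 and 1.23, and its other probes had moved less than the named one in MI against sham. Myh6 and Myh7 gave -0.46 ± 0.24 and -0.33 ± 0.23, which quantile normalization turns to 0.28 and 0.25. Bcl2l1 gave 0.78 ± 0.21 (adjusted p = 0.0684), with its other probes between -0.75 and -0.49. The lists of TPO and JAK-STAT signalling (median -0.07, adjusted p = 0.936), apoptosis (0.09, 0.312), platelet markers (-0.39, 0.287), endothelial markers (-0.15, 0.451) and macrophage markers (-0.70, 0.0571) did not pass.

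These counts depended on single arrays and on which arrays shared the estimate of the spread. The sham pair, which is not part of this comparison, had the smallest median SD (0.125). Without MI replicate 2 limma called 0 features, with 4606 at an unadjusted p under 0.05, without MI replicate 1 it called 267, without sham replicate 1 581, without sham replicate 2 580 and without MI+TPO replicate 1 4572; the 2 groups alone gave 582. Lists called numbered 5 without MI replicate 1, 18 without MI+TPO replicate 1 and 4 without MI+TPO replicate 2, of which 2 (fatty acid oxidation, and citric acid cycle and branched-chain breakdown) were among the 10.

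Whether TPO moved the genes of infarction the other way was examined over all features. Cnmd, AI231472 and AA926356 rose in MI and fell with TPO, 3 features where independent lists give 0.3669, and 0 fell in MI and rose with TPO, where they give 0.0443. Independent lists leave out the shared MI arrays, and of 100 simulations of unchanged groups with those arrays shared none gave over 1 feature. Few features of any kind are called in unchanged groups, so neither number is a baseline for this count. The log2 fold changes of the 2 comparisons correlated at -0.557 across features, and their covariance was -0.476. Both comparisons share the MI arrays, and unchanged groups simulated against those arrays gave a correlation of -0.499 and a covariance of -0.067, which leaves -0.41. With 1 MI array for each comparison the covariance was -0.287 and -0.497. Both MI arrays lay on the same slide, so an effect of that slide would stay in both values. The simulations held no such effect. Without any 1 of the sham or MI arrays, 0 features were called in both comparisons in opposite directions. Without MI+TPO replicate 1 they numbered 2443 and without MI+TPO replicate 2 they numbered 470.

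**Figure D3:**
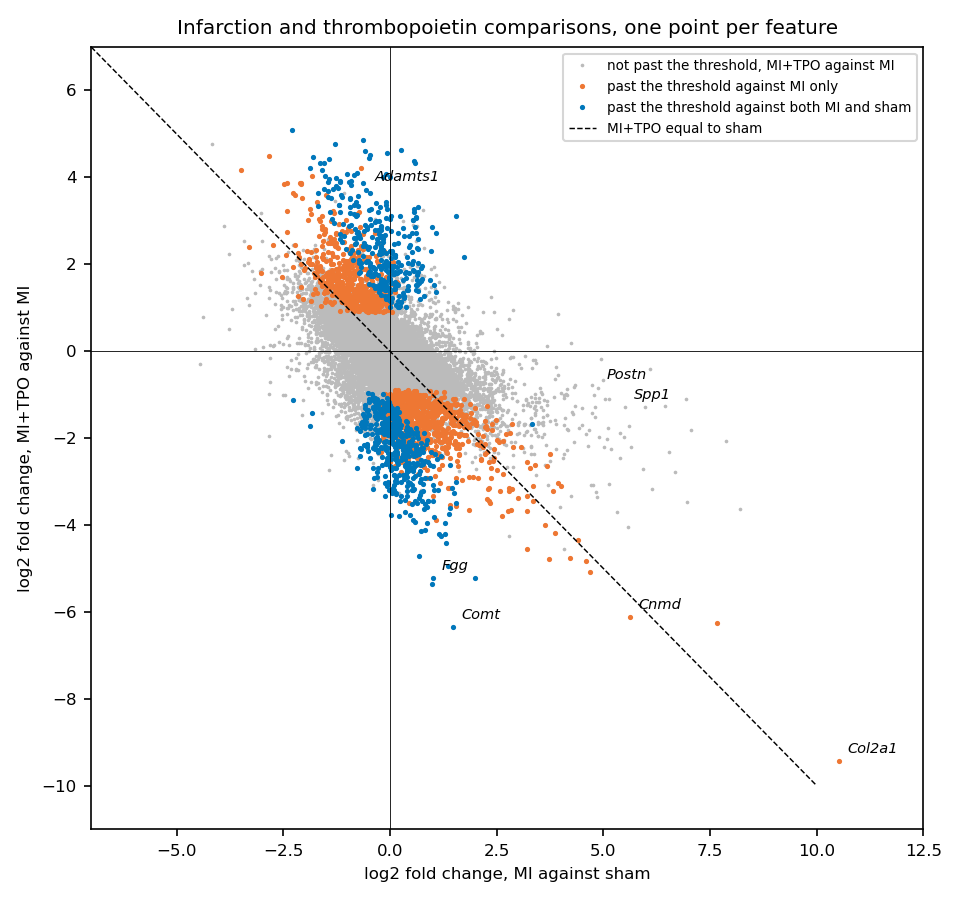
Log2 fold change of MI+TPO against MI (y axis) over that of MI against sham (x axis), 1 point per feature, with calls against MI in orange, calls against both MI and sham in blue and a dashed line where MI+TPO equals sham. Cnmd and Col2a1 lay near the dashed line, while Comt, Fgg and Adamts1 lay away from both sham and MI.

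The third comparison set infarcted hearts with TPO against sham. Matrix, protease, macrophage and stress genes were higher with MI+TPO, and erythroid and mesothelial genes were lower, as lists whose calls ended with an estimated correlation (adjusted p = 0.787). Without MI+TPO replicate 1 the macrophage call also ended, and without MI+TPO replicate 2 the erythroid and mesothelial calls did. Spp1 rose 18.8-fold, or 4.23 on the log2 scale, to 4.00 ± 1.94 (SD, n = 2; adjusted p = 0.0491; the call ended with quantile normalization). Its log2 fold change was 2.86 without MI+TPO replicate 1 and 5.60 without MI+TPO replicate 2, and Mmp12 (chromosome 8, 4259057 to 4259413) was at least 22-fold higher (adjusted p = 0.0158), or 11.4 and 42.5 without these arrays. The beta globin gene Hbb fell from 5.99 ± 0.02 (SD, n = 2) to 3.19 ± 0.23 (SD, n = 2; adjusted p = 0.0234), and Msln fell by 2.68 ± 0.36 (adjusted p = 0.0216). Comt fell by 4.88 ± 0.43 (adjusted p = 0.0141).

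Of the 37 lists 16 passed, 12 higher and 4 lower, none with an estimated correlation (adjusted p = 0.787 for all 16) or with fry (smallest adjusted p 0.325). All 41 matrix genes were higher (median 1.23, adjusted p = 3.05e-12), with Spp1 past all genes and 0 past the list alone. Of 21 proteases and inhibitors 20 were higher (median 0.96, adjusted p = 1.65e-07), 7 past the list alone and 4 over all genes, among them Timp3 at 1.18 ± 0.23, whose call ended with quantile normalization. After normexp background correction the members Mmp10 (-1.02) and Adamts1 (-0.03) turned, while Mmp12, Timp1 and Timp3 stayed positive. Natriuretic peptide and stress genes had a median of 0.43 (adjusted p = 0.00275), and 5 of 18 rose when adjusted over the list alone: Nppa (3.55 ± 0.80, or 2.29 without MI+TPO replicate 1 and 4.82 without MI+TPO replicate 2), Nppb (0.92 ± 0.24, its other probes between -0.51 and -0.43), Acta1 (1.5 ± 0.36), Xirp2 (1.25 ± 0.31) and the stretch-responsive Ankrd2 (1.1 ± 0.21), though Ankrd2 gave -0.58 after normexp background correction. Macrophage markers (median 0.80, adjusted p = 9.57e-06), chemokines (0.34, adjusted p = 0.00201) and MHC class II (0.55, adjusted p = 0.0037) were higher with 2, 1 and 3 members past the list alone. These 3 calls ended without MI+TPO replicate 1, at medians of 0.20, 0.18 and 0.41, and without MI+TPO replicate 2 the medians were 1.45, 0.66 and 1.59. Without sham replicate 1 the chemokine median was 0.62. The MHC class II member Ciita turned to -0.74 after normexp background correction. The matrix and protease medians were 0.50 and 0.34 without MI+TPO replicate 1, and 1.96 and 1.76 without MI+TPO replicate 2. The eosinophil chemokine Ccl11 was at least 7.24-fold higher (12.8 without MI+TPO replicate 1 and 4.11 without MI+TPO replicate 2), a call that ended after normexp background correction (0.34). Complement (0.45, adjusted p = 0.0177), cell cycle (0.32, 0.0177), mast cell (0.74, 0.0461), interferon-stimulated (0.30, 0.0342) and skeletal muscle (0.52, 0.0342) lists were also called. Cartilage and bone genes had a median of 1.03 (adjusted p = 0.0126) but 0.00 with 8 members at their bounds. Erythroid genes fell in 3 of 13 members adjusted over the list alone (median -0.73, adjusted p of the list 0.0177), with Slc4a1, the red cell anion exchanger, at -1.47 ± 0.20. Mesothelial markers fell in 7 of 12 (median -1.23, adjusted p of the list 0.0163) and Aldh1a2 rose, adjusted over the list alone. The respiratory chain (median -0.58, adjusted p = 7.44e-05) and the sarcomere (-0.51, adjusted p = 0.0498) were lower with 0 members past the list alone. With members at their bounds, the medians were 1.11 for matrix, 0.90 for proteases, 0.78 for macrophages, 0.57 for mast cells and 0.29 for cell cycle. Fatty acid oxidation (-0.59, adjusted p = 0.0892) and calcium handling (-0.49, 0.211) did not pass.

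Limma called 974 features here, 401 higher and 573 lower, or 41.2% higher. With quantile normalization 411 were higher and 344 lower, or 54.4% higher. After normexp background correction 979 were higher and 5156 lower, or 16% higher, so the balance of directions depended on the processing. The median of all features was -0.128 on the log2 scale in this comparison, and the list tests are relative to the other genes. The largest rises and falls below are again ranked by fitted log2 fold change, values below background included. Some of their bounds are smaller than the measured folds of Spp1, Hbb and Msln. The largest rises beside Mmp12 were Chodl (at least 15.3-fold), the fat cell hormone Adipoq (at least 14.1-fold), Ifna4 (at least 7.25-fold) and Mup4l3 (at least 24.4-fold). Without MI+TPO replicate 1 these 4 bounds were 6.5, 6.74, 12.7 and 11.2, and without MI+TPO replicate 2 they were 36, 29.6, 4.15 and 53.3. The largest falls beside Comt were Bnc1 (at least 11.5-fold lower), Fgg (at least 5.37-fold), Rims1 (at least 3.41-fold) and Upk3b (at least 2.8-fold). Adamts1 was at least 5.5-fold higher, but its log2 fold change was -0.03 and that of Ifna4 0.51 after normexp background correction. Of the 2102 features called in MI+TPO against MI, 777 were also called against sham in the same direction, 315 higher and 462 lower. Independent lists give 17.76 and 35.04, which leaves out the shared arrays. Simulated unchanged groups with the MI+TPO arrays shared gave 0. Few features of any kind are called in unchanged groups, so neither number is a baseline for this overlap. Both comparisons share the MI+TPO arrays: their log2 fold changes correlated at 0.498 and had a covariance of 0.408, where unchanged groups simulated against those arrays gave 0.501 and 0.067.

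Without sham replicate 1 or sham replicate 2 limma called 0 features in MI+TPO against sham, with 2707 and 2387 at an unadjusted p under 0.05, without MI replicate 1 295, without MI replicate 2 294, without MI+TPO replicate 1 365 and without MI+TPO replicate 2 4210, and the 2 groups alone gave 297. Without MI+TPO replicate 1, 6 lists were called (matrix, proteases, natriuretic peptide and stress, erythroid, skeletal muscle and mesothelial), the medians of complement (0.18), mast cell (0.37), interferon-stimulated (-0.03), cell cycle (-0.24), cartilage and bone (0.16), respiratory chain (-0.25) and sarcomere (-0.37) lists being no longer past the threshold. Without MI+TPO replicate 2 the erythroid (-0.76), skeletal muscle (0.62) and mesothelial (-1.04) calls ended, without sham replicate 1 that of skeletal muscle (0.57), and without sham replicate 2 those of complement (0.37), cell cycle (0.23), interferon-stimulated (0.07) and sarcomere (-0.37) lists. By scaling, the calls of the sarcomere, respiratory chain, mast cell and interferon lists ended with quantile normalization. With probes above background on all arrays the mast cell, cell cycle and skeletal muscle calls ended, and with the value table of the series that of the sarcomere did. After normexp background correction the calls of the mast cell (-0.15), erythroid (-0.79), cell cycle (-0.34), skeletal muscle (0.03) and cartilage and bone (-0.57) lists ended, and the respiratory chain (-0.15) and sarcomere (-0.06) lists turned up relative to other genes, neither of them past the threshold.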

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

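Chosen after seeing the data were normexp background correction (offset 50) on the median signals of all 6 arrays, the same on the mean signals of the sham and MI arrays alone, and the list tests with only the 2 groups compared. Normexp on the mean signals of all 6 arrays and a slide block were not run: the MI+TPO files hold no mean signal, and each slide holds 1 group. Unless stated otherwise, the cause was not tested. For named genes, 1326 results in MI against sham, 925 in MI+TPO against MI and 1111 in MI+TPO against sham kept their direction and side of the threshold. A further 442, 52 and 88 were now past it, and 32, 166 and 107 no longer were. In MI against sham only 5 of the called features had a symbol. Most of its 1326 unchanged results were therefore past the threshold in neither fit. Of list results, 276, 110 and 173 were the same and 60, 40 and 64 were no longer past the threshold. Signal over background limits the dim probes, where most turns of sign after normexp lie.

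The 7 features called in MI against sham became 833 with normexp on median signals (2 of the 7 among them), 1671 with normexp on mean signals (4 of the 7), 27 with quantile normalization and 14 with the mean of a gene's probes. With no filter on dim probes limma called 0 (7752 at an unadjusted p under 0.05), and with probes above background on all arrays 0 (5077 at that p). They became 3972 with only the 2 groups compared, 0 at an adjusted p under 0.01 and 3615 at an unadjusted p under 0.05 with at least 2-fold. Leaving out 1 array gave between 0 and 3967.

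The 2102 in MI+TPO against MI became 3737 with normexp (1623 of the 2102 among them), 10778 with no filter, 582 with the 2 groups, 355 at an adjusted p under 0.01 and 3840 at an unadjusted p under 0.05 with at least 2-fold; leaving out 1 array gave between 0 and 4572. The 974 in MI+TPO against sham became 6135 with normexp (769 of the 974), 649 with no filter, 482 with probes above background on all arrays, 297 with the 2 groups, 0 at an adjusted p under 0.01 (4984 at an unadjusted p under 0.05) and 3172 at an unadjusted p under 0.05 with at least 2-fold. Leaving out 1 array gave between 0 and 4210.

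The 3 features called in opposite directions became 307 with normexp, 19 with quantile normalization, 9 with the mean of a gene's probes, 195 with the 2 groups and 5 with an intensity trend in eBayes. They became 0 with no filter, with probes above background on all arrays and at an adjusted p under 0.01, and 1315 at an unadjusted p under 0.05 with at least 2-fold. Leaving out 1 array gave between 0 and 2443. An array left out leaves its group with 1, which is assumed to vary like the others.

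The 21, 10 and 16 lists called became 0 in each comparison with camera at an estimated correlation and 0 with fry. With no filter on dim probes 14 of the 21 kept their call, and basement membrane, mast cell, chemokine, MHC class II, cell cycle, immediate early and skeletal muscle lists did not. Of the 10, the 5 lower lists ended there and the 5 higher were kept, and of the 16 the sarcomere and skeletal muscle lists ended. With normexp on median signals glycolysis and skeletal muscle ended among the 21, TGF-beta signalling among the 10, and mast cell, erythroid, cell cycle, skeletal muscle and cartilage lists among the 16, of which 9 were kept and 2 turned. With normexp on mean signals glycolysis, cell cycle and skeletal muscle ended among the 21. With probes above background on all arrays MHC class II ended among the 21, cartilage and bone among the 10, and mast cell, cell cycle and skeletal muscle among the 16. Quantile normalization ended glycolysis among the 21 and sarcomere, respiratory chain, mast cell and interferon lists among the 16, and the value table ended the sarcomere there. Leaving out 1 array gave between 18 and 23, between 4 and 18, and between 6 and 20. An array left out can change which probe of a gene is brightest: in MI+TPO against MI without a sham array the cartilage and bone median was -2.45 for that reason, and -1.11 with the probes kept.

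With the replicate number as a block, the counts were 2739, 3394, 2406 and, for opposite directions, 958, and the lists called 21, 12 and 19. Nothing in the labels says that the numbers pair the samples. The deviations of replicate 1 correlated across genes at 0.106 between sham and MI, 0.152 between sham and MI+TPO and 0.361 between MI and MI+TPO.

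Directions turned as follows, in log2 fold change. With normexp on median signals, MI against sham gave Acta1 0.29, Myh7 0.21, Myh6 0.02 and Ciita -0.40. MI+TPO against sham gave Atp2a2 0.21, Myh7 0.06, Chad -0.57, Nusap1 -1.06, Dhx58 -0.21, Fcer1a -0.95, Ms4a2 -0.16, Adamts1 -0.03, Mmp10 -1.02, Ciita -0.74, Ankrd2 -0.58 and Mybpc2 -0.12. There the camera direction of the sarcomere (median -0.06) and respiratory chain (median -0.15) lists turned up relative to other genes. With normexp on mean signals, MI against sham gave Acta1 0.27, Myh7 0.22, Myh6 0.02 and Ciita -0.41. With quantile normalization Acta1 was 0.14 and Myh7 0.04 in MI against sham, Myh7 0.25 and Myh6 0.28 in MI+TPO against MI, and Atp2a2 0.02, Myh7 0.29 and Myh6 0 in MI+TPO against sham. Scaling by the median of detected probes gave Acta1 0.01 in MI against sham. With the mean of a gene's probes Asph was 0 in MI against sham, Bcl2l1 -0.15 in MI+TPO against MI, and Nppb -0.01 and Bcl2l1 -0.57 in MI+TPO against sham, since their probes differ in sign. Without sham replicate 2, Acta1 was 0.08 and Myh7 0.09 in MI against sham and Atp2a2 0.04 in MI+TPO against sham. Leaving out 1 array gave, in MI against sham, Acta1 between -0.24 (without MI replicate 2) and 0.22 (without MI replicate 1) and Myh7 between -0.19 and 0.13, without the same arrays. In MI+TPO against sham it gave Atp2a2 between -0.45 (without MI+TPO replicate 2) and 0.09 (without MI+TPO replicate 1), and the cell cycle list between -0.24 (without MI+TPO replicate 1) and 0.82 (without MI+TPO replicate 2). In MI+TPO against MI it gave Nppa between -2.03 and 0.49, Postn between -2.32 and 0.63, Timp1 between -1.79 and 0.09, and Spp1 between -2.67 and 0.08, the lower without MI+TPO replicate 1 and the higher without MI+TPO replicate 2.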

Other observations

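Chosen after the result was seen were the tests of the shared MI arrays, of a smaller share of infarcted tissue and of chest-wall tissue. Several gene groups outside the lists called in MI against sham held members that passed when adjusted over the list alone. Among endothelial markers these were the lymphatic marker Lyve1 (1.34 ± 0.25), Vwf (0.88 ± 0.21) and Plvap, which was not well above background in sham, all higher in MI. Flt4 also passed, but it was well above background in neither group, so no rise is shown. Of the 23 endothelial markers above background, 3 passed. Among angiogenic factors 7 rose, including Igf1 (2.51 ± 0.43), Vegfd (2.72 ± 0.67) and Angpt2 (1.97 ± 0.45), and Vegfb (-1.73 ± 0.51), Dll4 (-1.15 ± 0.33) and Apln (-1.05 ± 0.27) fell (median of the list 0.24, adjusted p = 0.258). The angiotensin system genes Agt, not well above background in sham, and Ace (1.25 ± 0.22) rose. Socs3, an inhibitor of cytokine signalling, also passed, but it was well above background in neither group, so no rise is shown. Of the 23 members of its list above background, 0 passed. Among adipocyte markers Adipoq and Retn rose and 4 members fell, so that the median (-0.96) and the mean (1.06) differ in sign.

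In MI+TPO against MI, members of lists that were not called also moved. Plvap (-2.54 ± 0.32), Ccl19 (-1.67 ± 0.35), Il33 (-1.51 ± 0.25) and the mast cell tryptase Tpsab1 (-1.34 ± 0.25) fell, and the neutrophil gene S100a8 (1.51 ± 0.27) rose, over all genes. Of 13 erythroid genes, 5 fell when adjusted over the list alone, led by Hbb (-2.29 ± 0.38); the list itself did not pass (adjusted p = 0.144). Sos1, an exchange factor that activates Ras, rose by 0.92 ± 0.21 (adjusted p = 0.0478) over all genes.

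MI+TPO replicate 2 lay near sham on the axis from sham to MI (0.07), while MI+TPO replicate 1 (0.57) lay beside MI replicate 2 (0.61). Chance values of the shared MI arrays that are independent between genes are argued against, since the covariance of the fold changes was -0.476 and 100 simulations lay between -0.07 and -0.063. Those simulations drew each gene independently. On the real arrays genes moved together: the difference between the MI+TPO replicates correlated at 0.662 with that between MI and sham. Chance differences between animals that move many genes at once were therefore not excluded. Over 310 members of 19 lists, selected for their MI difference, 47.9% of the MI difference was left with TPO, but 83.5% on MI+TPO replicate 1 and 11.1% on MI+TPO replicate 2. A smaller share of infarcted tissue in the samples would leave about the same share in every list. By intervals over list members, 3 of the 19 lay apart from it: mast cell (32.6%), complement (29.6%) and the respiratory chain (58.6%). These rest on 4, 15 and 53 members. The members share the same 2 MI+TPO arrays, so these intervals leave out the spread between arrays. The count of 3 also lies between the bounds set for the test. An effect of TPO and a difference in the tissue sampled, or in infarct size, therefore cannot be told apart and each may contribute. An effect of the slide that both MI arrays share cannot be told apart from these either.

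On 777 features MI+TPO lay apart from both sham and MI in 1 direction. Clusters of neighbouring spots are argued against, with 0.96 times the neighbouring pairs of random placements (51 against 53.3, with 95% of placements between 40 and 67). A weak gradient over the slide was not tested. Of 26 genes with another probe, 88.5% had it moving the same way, with a 95% exact binomial interval from 69.8 to 97.6 that spans the bound set, and 80.9% of other genes moving at least 2-fold did so. With quantile normalization 73.4% (570) were still called, all 777 kept their sign, and the median absolute log2 fold change went from 2 to 1.88, so a trend with intensity may account for part. TPO, the slide and the scanner cannot be told apart, since the MI+TPO group alone was read on the other scanner.

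Cartilage and bone genes were high on both MI arrays, and Comp was at 4.98 on MI+TPO replicate 1 and -1.77 on replicate 2. The log2 fold change of Comp, a cartilage matrix protein, was 8.21 ± 1.98 in MI against sham, and most other cartilage markers were at background in sham. Skeletal muscle markers were called higher too. In a set of 11 measured muscle genes, including the slow-muscle troponins Tnnt1 (0.56) and Tnni1 (0.28), 4 were at least 2-fold higher (median 0.56). These were Myl1, at least 23-fold higher, Tnnt3 and Mybpc2, each at 1.47, and Tnnc2 at 1.07 ± 1.48. Ckm (-1.47), Eno3 (-1.39) and Acta1 (-0.01) were not higher. Their sham levels were 8.38, 7.94 and 4.15, a heart baseline that could hide carried-over muscle. Of 5 fast muscle genes without a sham signal on both arrays, 20% were well above background on both MI arrays (Myl1, but not Myh4, Pvalb, Atp2a1 or Ryr1), with a 95% exact binomial interval from 0.5 to 71.6, so these genes are too few to decide. Chest-wall tissue carried over at dissection and cartilage-like cells in the scar cannot be told apart here, and either may give this pattern.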
